A study of Mus musculus with 2 samples.

How the data were processed

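Liver RNA of mouse embryos was measured in 2 libraries, which the labels name biological replicates 1 and 2 of 1 group. Replicate numbers are those of the labels. The aligner and its version are not given in the sources used here.

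For each library the authors deposited a gene and a transcript table. Per the file headers these hold an expected count (an estimated count per gene that need not be whole), TPM and FPKM, with a length and an effective length in nucleotides. The deposited TPM sums to the same total in both libraries over all rows, spike-ins included, and the deposited FPKM is per kilobase of effective length. The transcript tables hold the percent of a gene's abundance assigned to each transcript, per the file headers. A deposited note names the mm10 assembly and annotation M4 for these tables and says that they came from alignments to the transcriptome. A second set on the mm9 assembly holds annotated (Ensembl) and de novo (Cufflinks) gene, exon and transcript models with RPKM of 2 replicates, per the file headers. It is not stated which of these replicates is which library, so their mean was used. The authors also deposited contigs with a coverage signal and splice junctions with a read count, each with an irreproducible discovery rate (IDR), which like a p-value is smaller for features that the replicates share. The junction names carry a flag that marked all 168883 junctions matching an annotated intron and no other, and a second flag that was not used here.

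Gene identifiers were matched without version to GENCODE M21, on the same build as mm10, and 42462 of 43346 got a symbol. Of 437 genes on the lists 434 were found. These lists and the rule for named genes were fixed before the data were examined, and 5 further lists were written later for the tests of the closing part (second neural and gut lists, Y-linked genes, X-linked genes that escape inactivation, and decidual and placental genes). The rule takes the 20 genes of highest mean TPM, up to 4 leading members of each list and members at 0, and all globins. It adds the 5 largest called differences each way among named genes with a mean of at least 1 TPM, the 5 largest isoform moves and the 3 highest contigs outside genes. The called list members named beyond these, Cps1, Hamp, Uty and the genes that the closing part alone names were chosen after their values were seen. Some genes that the rule takes are not reported here. Rows of spike-ins (2.84% of counts in replicate 1 and 1.82% in replicate 2), phiX (0.0764% and 0.0857%) and 26248 rows with numeric identifiers (2 counts and 0 counts) stayed out of library sizes and tests. Wilson 95% intervals were used for these shares.

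Expected counts were rounded to whole numbers. With 1 group, edgeR's quasi-likelihood test has no groups to compare. The libraries were therefore compared by a two-sided exact conditional binomial test per gene with TMM effective library sizes, Benjamini-Hochberg adjustment over genes with at least 10 counts in all, and calls at an adjusted p under 0.05 and at least 2-fold. Fold changes add 0.5 to each count. The p-values measure the difference of these 2 libraries. edgeR 4.0.16 gave TMM factors and the common dispersion, DESeq2 1.42.0 gave size factors, under R 4.3.3. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 did the rest. On simulated counts for the comparison of replicate 2 with replicate 1, with counting noise only, 93.7% of 95 genes changed 3-fold and 90.9% of 99 changed 6-fold were recovered among 17886 tested, and 1 unchanged gene was called. With the spread of the housekeeping genes added, 91.8% of 97 and 97% of 99 were recovered among 17880 tested, and 273 unchanged genes were called.

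List levels are medians of TPM, set against 10000 random lists drawn from genes with a count in either library. List differences are medians of log2 TPM ratios (0.01 added to TPM) over members with a mean of at least 1 TPM, set against 10000 random lists matched on mean TPM in 20 bins. At least 5 such members were required. In the closing part the lists of other organs and the second neural and gut lists, which hold low genes, had a minimum of 0.05 TPM, and 3 members were enough for these and for the Y-linked and escape lists. GC content is that of the GENCODE transcripts weighted by TPM and was known for 99.8% of genes with a mean of at least 1 TPM. Trends were fitted by lowess with a span of 0.3. In the mm9 gene table each gene has a pair of lines, of which 1 was used. The text gives the results of the 5 later lists in the closing part. Alternatives covered the library sizes, count and TPM minimums, units, pseudocounts, the mm9 tables and single replicates. Leaving out a replicate is not possible for a comparison of the 2 libraries. No outlier test or comparison of groups applies to 1 group of 2.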

Results

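Polyadenylated RNA longer than 200 nt was sequenced from the liver of C57BL/6J mouse embryos at embryonic day 14.5, when the organ is the main site of red cell formation as well as the developing liver. The labels describe stranded paired-end libraries, made from littermates of mixed sex. The series holds 1 group of 2 biological replicates and no contrast between conditions, so the data give levels in the organ and the difference between its replicates. The gene tables held 102720906 estimated counts on genes in replicate 1 and 65640929 in replicate 2. At these depths a count of 0 allows a level of up to 0.0292 CPM (counts scaled to library size) in replicate 1 and 0.0457 CPM in replicate 2. Confidence intervals and these limits cover counting error only, since the reads carry no molecular identifiers. Nothing in the labels says how many litters were pooled. A level of at least 1 TPM, the authors' abundance unit scaled for transcript length and library size, was reached by 11209 genes in both libraries. All values below are means ± SD over n = 2 libraries unless stated otherwise, and gene positions are in build mm10.

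Globin transcripts took a large share of both libraries. The 10 measured globin genes, which encode the protein chains of hemoglobin, held 25.6% of gene counts in replicate 1 and 28.1% in replicate 2. On TPM, which weighs short genes more, they held 48.5% and 57.5%. The adult-type alpha globin genes Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298) and Hba-a1 (chromosome 11, 32283511 to 32284465) stood at 279147 ± 108250 and 43147 ± 22065 TPM. These near-identical copies share reads, so their split is uncertain and their sum is used below. The adult-type beta globins Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) and Hbb-bt (chromosome 7, 103812524 to 103813996) reached 134930 ± 12370 and 72218 ± 10239 TPM and are likewise close copies. The embryonic beta-type genes of the primitive red cell lineage were far lower, with Hbb-y at 345.5 ± 25.2 TPM and Hbb-bh1 at 117 ± 32.8 TPM. Adult-type exceeded embryonic beta globin by 8.80 ± 0.13 on the log2 scale, a ratio of 477 in replicate 1 and 418 in replicate 2. Adult-type alpha globin exceeded the embryonic Hba-x, at 34.6 ± 5.41 TPM, by 13.17 ± 0.16 on the log2 scale. The theta-type genes Hbq1b and Hbq1a stood at 138.6 ± 22.6 and 8.22 ± 0.728 TPM, and Hbb-bh2 at 0.12 ± 0.071 TPM. With 2 libraries an exact sign test cannot go below p = 0.5, so no test was made of these ratios. In the mm9 tables of the same experiment both ratios were smaller, at 6.96 for beta and 11.28 for alpha on the log2 scale.

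**Figure D1:**
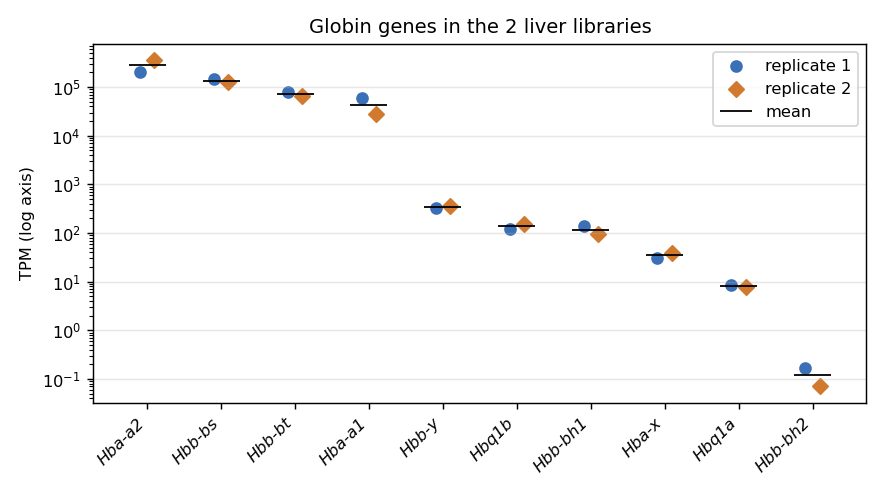
TPM of the 10 measured globin genes on a log axis, with a circle for replicate 1, a diamond for replicate 2 and a line for their mean. The 4 adult-type genes lie between 27545 and 355692 TPM, and the embryonic Hbb-y, Hbb-bh1 and Hba-x between 30.7 and 363.4 TPM.

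Red cell genes other than globins were also high. The median of the 29 measured erythroid genes was 143 ± 9.75 TPM, 18 of them reached 100 TPM in both libraries, and all 29 reached 1 TPM. The list was led by Car2, a carbonic anhydrase gene, at 1243 ± 290 TPM. Alas2, the first enzyme of heme synthesis in red cells, stood at 958.6 ± 20.8 TPM. Slc4a1, the band 3 anion exchanger, followed at 585.8 ± 54.9 TPM and Slc25a37, the mitochondrial iron importer, at 464.6 ± 9.79 TPM. The 13 heme synthesis genes had a median of 232 ± 33.6 TPM. Urod stood at 417.8 ± 5.93 TPM. Alas2 and Slc25a37 belong to both lists. Among the 15 iron genes Trf (transferrin), Ftl1 and Fth1 (ferritin chains) and Tfrc (transferrin receptor) were highest, at 2163 ± 269, 1809 ± 71.7, 1479 ± 182 and 187.2 ± 52.8 TPM. Hamp2, a hepcidin gene, was at 0 in both libraries, while the hepcidin gene Hamp of the same list stood at 12.9 ± 1.96 TPM.

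Genes of hepatoblasts and hepatocytes were also high. All 30 members reached 1 TPM in both libraries, 18 reached 100 TPM, and the median was 193.9 ± 33 TPM. Alb (albumin, ENSMUSG00000029368, chromosome 5, 90460897 to 90476602) stood at 9617 ± 998.6 TPM and its fetal relative Afp (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907) at 5866 ± 2108 TPM. Apoa2 reached 2937 ± 279 TPM. The log2 ratio of the erythroid to the hepatocyte median was -0.43 ± 0.34, with -0.67 in replicate 1 and -0.19 in replicate 2, so both libraries had the lower erythroid median. With summed TPM in place of medians the ratio was -2.17, and with the globin genes added to the erythroid sum it was 4.17. The order of the lineages thus turned on whether globins were counted.

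Lists of secreted plasma proteins, those of coagulation and complement, had higher medians than the late hepatocyte and bile acid lists. All 16 coagulation genes reached 1 TPM, with a median of 63.4 ± 4.36 TPM. Serpinc1 (antithrombin), Fgg (fibrinogen gamma chain), Kng1 (kininogen) and F2 (prothrombin) stood at 260.1 ± 51.1, 204.3 ± 49.7, 194.6 ± 33.8 and 182.9 ± 15.4 TPM. Of 16 complement genes 13 reached 1 TPM in both libraries, led by C3 at 214.5 ± 3.45 TPM and Cfb at 127.5 ± 36.2 TPM. The 15 cholesterol synthesis genes had a median of 28.8 ± 3.33 TPM, and Fdps was highest at 120.4 ± 1.41 TPM. The 24 late hepatocyte genes had a median of 0.52 ± 0.099 TPM and 11 of them reached 1 TPM in both libraries. Glul (65.2 ± 26.8 TPM) and Hpd (27.6 ± 1.54 TPM) were among its higher members, and Cyp2c29, Mup20 and Mup3 were at 0 in both libraries. The 9 bile acid genes had a median of 0.685 ± 0.035 TPM. Cyp27a1 was highest at 2.81 ± 0.446 TPM and Abcb11, the bile salt export pump, stood at 2.6 ± 1.07 TPM. All 6 urea cycle genes reached 1 TPM. Ass1 was highest at 57.5 ± 6.48 TPM and Cps1 lowest at 1.11 ± 0.092 TPM.

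A few imprinted genes were among the most abundant. The long noncoding RNA H19 stood at 3278 ± 340 TPM, Dlk1 at 1068 ± 148 TPM, the growth factor gene Igf2 at 966.8 ± 10.7 TPM and Meg3 at 871.3 ± 59.8 TPM. Of the 19 imprinted genes 18 reached 1 TPM in both libraries, with a list median of 26.6 ± 4.86 TPM. The 10 genes of the fetal program had a median of 4.83 ± 0.53 TPM. They include H19, Dlk1 and Igf2, followed by Igf2bp3 at 5.67 ± 1.36 TPM, and the list's median lay within the range of random lists (percentile 87.2). Genes of the cell cycle were high, with a median of 100.5 ± 6.7 TPM over 19 genes. Pcna stood at 362.4 ± 16.7 TPM, Cdk1 at 189.9 ± 96.6 TPM, Birc5 at 148.4 ± 37.4 TPM and Ccna2 at 127.7 ± 29.1 TPM.

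Other blood lineages were detected at lower levels. The 15 granulocyte and mast cell genes had a median of 36 ± 4.38 TPM, led by S100a8 at 499.4 ± 145 TPM, S100a9 at 351.3 ± 87.9 TPM and Mpo (myeloperoxidase) at 147.4 ± 16.3 TPM. The 14 macrophage genes had a median of 14.1 ± 2.38 TPM, with Lyz2 at 96.2 ± 0.976 TPM and C1qb at 60.9 ± 7.59 TPM. The 11 megakaryocyte genes had a median of 11.5 ± 0.976 TPM, with the platelet chemokine genes Pf4 at 245.9 ± 27.7 TPM and Ppbp at 134.1 ± 15.2 TPM. All members of these last 2 lists reached 1 TPM. Stem and progenitor genes had a median of 2.79 ± 0.163 TPM. Their highest members were Gfi1b at 77.7 ± 11.6 TPM and Myb at 13.9 ± 1.76 TPM, both of which are also used by committed blood cells. B lymphoid genes had a median of 0.21 TPM in each library, with 3 of 11 reaching 1 TPM, namely Cd79b, Igll1 and Vpreb1. T and NK cell genes had a median of 0.0475 ± 0.0035 TPM, with Nkg7 and Lck reaching 1 TPM among 8.

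Nonblood cells of the organ were represented as well. The 11 endothelial genes all reached 1 TPM, with a median of 5.51 ± 0.834 TPM and Egfl7 highest at 63.1 ± 2.84 TPM. The sinusoidal scavenger receptor genes Stab1 and Stab2 stood at 18.9 ± 1.14 and 10.4 ± 0.149 TPM. The 14 stellate and mesenchymal genes had a median of 6.96 ± 1.76 TPM, with Col3a1 at 27 ± 13.2 TPM, Dcn at 26.9 ± 2.13 TPM and Reln at 26.1 ± 6.36 TPM. Niche factor genes had a median of 6 ± 1.18 TPM, with Cxcl12 at 40.8 ± 1.78 TPM below Dlk1 and Igf2. Cholangiocyte genes (median 0.68 ± 0.014 TPM, Spp1 highest at 2.88 ± 1.01 TPM) and mesothelial genes (median 0.613 ± 0.095 TPM, Upk3b highest at 3.35 ± 0.7 TPM) were low. Lists of genes from pancreas, stomach and gut, lung, heart, skeletal muscle, neural tissue, and kidney and adrenal gland had medians of 0.0375, 0.102, 0.005, 0.173, 0.0775, 0.295 and 0.04 TPM. The highest of their members was the muscle gene Mylpf at 9.23 ± 2.75 TPM. Sftpb, Sftpc, Nppa and Gkn1 were at 0 in both libraries.

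Of the 36 lists, 15 had a median above the central 95% of 10000 random lists of equal size drawn from detected genes. They were the globin, erythroid, heme, hepatocyte, cholesterol, coagulation, complement, iron, granulocyte, macrophage, megakaryocyte, imprinted, proliferation, housekeeping and nonpolyadenylated lists. Those of T and NK cells, pancreas, lung, and kidney and adrenal gland lay below the central 95%. The megakaryocyte list left the upper range when protein-coding genes alone served as background or when the mm9 table was used. With replicate 1 alone 5 lists lay below the range, the stomach and gut list in addition to the 4. With replicate 2 alone the lung and pancreas lists were the 2 below the range. With the protein-coding background 7 lists lay below it, the late hepatocyte, muscle, and stomach and gut lists in addition to the 4 above. On mm9 values 6 did, the heart and muscle lists in addition to the 4. The 13 housekeeping genes had a median of 151.6 ± 2.53 TPM, with Eef1a1 at 3227 ± 1004, Ppia at 1550 ± 209, Gapdh at 1540 ± 73.3 and Actb at 829.3 ± 82.8 TPM. The 15 genes of RNAs that mostly lack poly(A) tails had a median of 43.4 ± 1.97 TPM. Rn7sk led at 1829 ± 152 TPM, with the copies Rn7s1 and Rn7s2 each at 372.3 ± 83.4 TPM and Rmrp at 130.1 ± 33.8 TPM. Rn7s1, Rn7s2 and Rmrp are shorter than the mean fragment of 302.7 nt in replicate 2. Their TPM estimates are therefore not reliable, and the list median includes them. The list members Rny1, Rny3 and Rprl3 were listed at 0, but all 3 are also shorter than this mean fragment. In the mm9 table Rny1 stood at 0.594 RPKM and Rny3 at 1.74 RPKM, so the 0 of these members is not read as absence. The last of the lists, 14 immediate early and stress genes, had a median of 3.08 ± 0.933 TPM, with Dnajb1, Dusp1, Ier3 and Junb highest at 38.6 ± 4.94, 25.2 ± 1.83, 10.3 ± 0.269 and 8.98 ± 1.73 TPM.

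**Figure D2:**
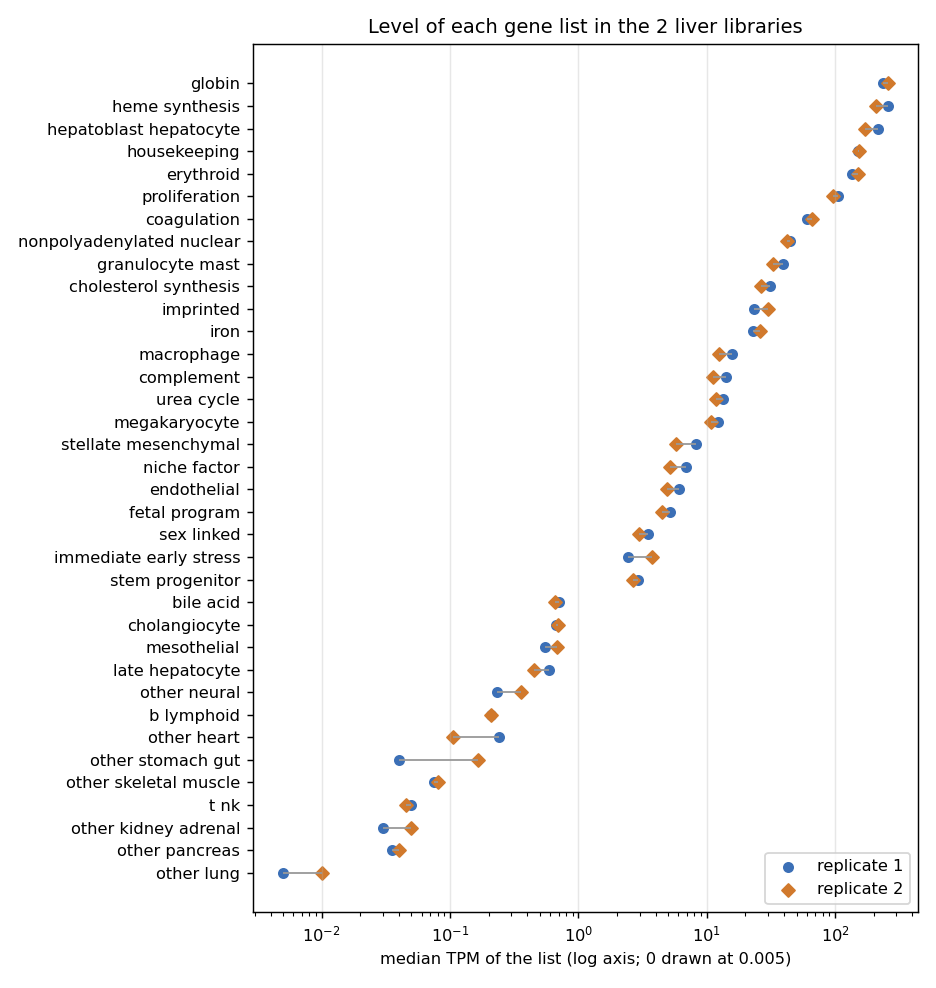
Median TPM of each of the 36 gene lists on a log axis, with a circle for replicate 1 and a diamond for replicate 2, and a median of 0 drawn at 0.005. The globin, heme, hepatocyte, housekeeping and erythroid lists lie above 100 TPM in both libraries, and the lists of other organs lie below 1 TPM.

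The 20 nuclear genes of highest mean TPM comprised the 4 adult-type globins, Alb, Afp, Apoa2, Trf and H19 given above, and 5 ribosomal protein genes. These 5 were Rplp1 (6661 ± 1022 TPM), Rps12 (5014 ± 214 TPM), Rps2 (2124 ± 171 TPM), Rps15 (2016 ± 8.66 TPM) and Rps26 (1994 ± 500.3 TPM). The rest were the metallothionein gene Mt1 at 3555 ± 657 TPM, the peroxidase gene Gpx1 at 3305 ± 353 TPM, Eef1a1, and 3 gene models without a descriptive name. These were Gm42418 (4564 ± 1741 TPM) and Gm10076 (3122 ± 994 TPM), which the annotation classes as lincRNA, and the unprocessed pseudogene Gm29216 (2883 ± 1327 TPM). Whether the reads of these 3 models come from the annotated loci was not tested, so they are not read as liver noncoding RNAs. Ribosomal protein genes and pseudogenes share reads with similar loci, so these levels are uncertain. Of the mitochondrial genes, kept apart, mt-Co2 stood at 3014 ± 160 TPM and mt-Co1 at 2988 ± 405 TPM. mt-Atp8 was listed at 12952 ± 7079 TPM, but its 204 nt are shorter than the mean fragment, so this estimate is not reliable.

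Which genes differed between the replicates was asked next. The largest difference among named genes with a mean of at least 1 TPM was in Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), the noncoding RNA of X inactivation in female cells. It had 98 counts in replicate 1 and 33082 in replicate 2, and was 526-fold higher in replicate 2 (log2 9.04, 95% exact interval 8.76 to 9.35). The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were present in both libraries, at 19.8, 8.77, 3.49 and 3.53 TPM in replicate 1 and 10.9, 4.1, 1.86 and 1.47 TPM in replicate 2. None of these 4 reached a 2-fold count difference. Also higher in replicate 2 were the histone gene Hist1h2ad (8.68-fold), the neuronal tubulin gene Tubb3 (6.52-fold, from 0.67 to 3.8 TPM) and the ribosomal protein pseudogenes Rpl7a-ps11 (8.36-fold) and Rps2-ps6 (5.84-fold). The 5 largest differences in the other direction were in Llph-ps2, Rpl35a-ps6 (19.8-fold), Scarna13, and the U3 RNA copies Rnu3b1 and Rnu3b3. Llph-ps2 had 640 counts in replicate 1 and 3.49 in replicate 2, a log2 ratio of -6.87 with a 95% exact interval of -9.37 to -5.53. Scarna13 had 71 counts and 2 counts, a log2 ratio of -4.19 with an interval of -7.57 to -2.60. The U3 copies had 11.4 estimated counts each in replicate 1 and 0 in replicate 2 (adjusted p = 0.0162, exact binomial test). Pseudogenes, histone genes and RNA copies share reads with near-identical loci, so their differences are uncertain. Scarna13, of 275 nt, and the U3 copies, of 216 nt, are also shorter than the mean fragment of replicate 2.

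Over all genes, 1436 of 17906 tested differed at least 2-fold with an adjusted p under 0.05, by an exact binomial test of the counts of the 2 libraries. Of these 642 were higher and 794 lower in replicate 2. Without processed pseudogenes and genes under 600 nt the balance turned, with 584 higher and 436 lower. The test compares these libraries and not conditions. With a mean of at least 1 TPM, 396 of the called genes remained, 66 higher and 330 lower, of which 199 were protein-coding and 131 processed pseudogenes. With spike-in counts as library sizes 3795 genes were called and 92.9% of them were higher in replicate 2, against 44.7% with TMM sizes. On simulated counts in which unchanged genes varied by the spread of the housekeeping genes, the binomial test called 273 of them. With an edgeR exact test that allows for the spread of housekeeping genes 580 genes were called. The 273 and 580 calls both rest on the spread of the 13 housekeeping genes. That spread was below those of the tested genes and the spike-ins given next, so these calls do not allow for the full spread of the tested genes. The common coefficient of variation beyond counting error was 24.9% over the tested genes and 17.3% over the 13 housekeeping genes. Over 71 spike-ins, which are added controls, it was 28.7%, so these values are not read as biological spread. Across genes, log2(TPM + 1) of the libraries correlated with Pearson r = 0.989 and Spearman rho = 0.949. Genes are not independent replicates, so no p is given.

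Most lineage lists held few called genes. None of the 29 erythroid, 13 heme, 16 coagulation, 16 complement, 19 proliferation, 14 macrophage, 11 endothelial or 14 stellate genes was called. Fabp1 was lower in replicate 2 among 30 hepatocyte genes, Cyp2f2 among 24 late hepatocyte genes, and S100a8 and Mcpt8 among 15 granulocyte genes. These calls rest on counts, and on TPM S100a8 differed by less than 2-fold, with 601.8 TPM in replicate 1 and 396.9 TPM in replicate 2. Gp1bb was higher among 11 megakaryocyte genes and Cd3g among 8 T and NK cell genes. The calls of Cyp2f2 (43 counts in replicate 1 and 13 in replicate 2) and Cd3g (9 and 18 counts) rest on few counts. Cyp2f2 stood at 0.21 and 0.08 TPM and Cd3g at 0.09 and 0.25 TPM. On TPM Gp1bb too differed by less than 2-fold, with 13.6 TPM in replicate 1 and 19.4 TPM in replicate 2. Hspa1a and Hspa1b, near-identical genes of inducible heat shock proteins whose split is uncertain, were higher among 14 immediate early and stress genes, at 2.42 against 0.87 TPM and 3.54 against 1.43 TPM. Of 8 neural genes 6 were higher, among them Tubb3, Stmn2, Sox10, Elavl3 and Elavl4, while Map2 and Gap43 were not called. Of 8 stomach and gut genes Sox2, Cdx1 and Cdx2 were higher, as were Nkx2-1 of the lung list and Myh7 of the heart list, and Myh8 of the muscle list was lower. Each of these 6 stood at no more than 0.18 TPM in either library. Among 15 nonpolyadenylated RNAs the counts of Rn7sk, Rn7s1, Rn7s2, Rmrp and Rpph1 were lower in replicate 2. On TPM, which divides by a length that depends on the fragments, Rn7sk went the other way, with 1722 TPM in replicate 1 and 1937 TPM in replicate 2. The others differed by less than 2-fold on TPM, with 431.3 and 313.4 TPM for each of Rn7s1 and Rn7s2, 154 and 106.2 TPM for Rmrp, and 46.8 and 42 TPM for Rpph1. Rn7s1, Rn7s2 and Rmrp are also shorter than the mean fragment of replicate 2. In each list the number adjusted over the list alone was the same as over all genes. The median log2 TPM ratio of replicate 2 over replicate 1 was -0.23 over all 11631 genes with a mean of at least 1 TPM. TPM sums to a fixed total, of which globins held 48.5% in replicate 1 and 57.5% in replicate 2. On counts with TMM sizes the median was -0.015 over 11572 tested genes of that level, so the TPM shift is not read as a general fall. Against matched random lists, the immediate early and stress list (median 0.30, 100th percentile) and the megakaryocyte list (median 0.12, percentile 99.3) lay above the central range, and the sex-linked list (median -0.90, percentile 0.355) lay below it. The other 21 lists with enough members lay within it. With the GC trend removed, the medians relative to all genes went from 0.54 to 0.22 for the stress list (percentile 97.9) and from -0.67 to -0.40 for the sex-linked list (percentile 1.34), and the iron list (percentile 98.2) and the nonpolyadenylated list (percentile 0.21) left the range. On TMM-normalized counts the nonpolyadenylated list was below the range (percentile 0) and the erythroid list above it (percentile 99.3). The stress list left the upper range, at percentile 94.2, when members had to reach a mean of 5 TPM, and the stellate list then lay below (percentile 1.68).

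The ratio of the libraries followed the GC content of the gene. Genes were placed in 10 bins of nearly equal size by GC content. In the lowest bin, 25.6% to 42.5% GC, the median log2 TPM ratio of replicate 2 over replicate 1 was -0.56, and in the highest bin, 58.2% to 72.8% GC, it was 0.14. Spearman's rho between GC content and the ratio was 0.548 across 11607 genes. For transcript length rho was -0.0451 with the TPM ratio and 0.12 with the count ratio on which the calls rest. The mean fragment implied by the effective lengths was 214.2 nt in replicate 1 and 302.7 nt in replicate 2.

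**Figure D3:**
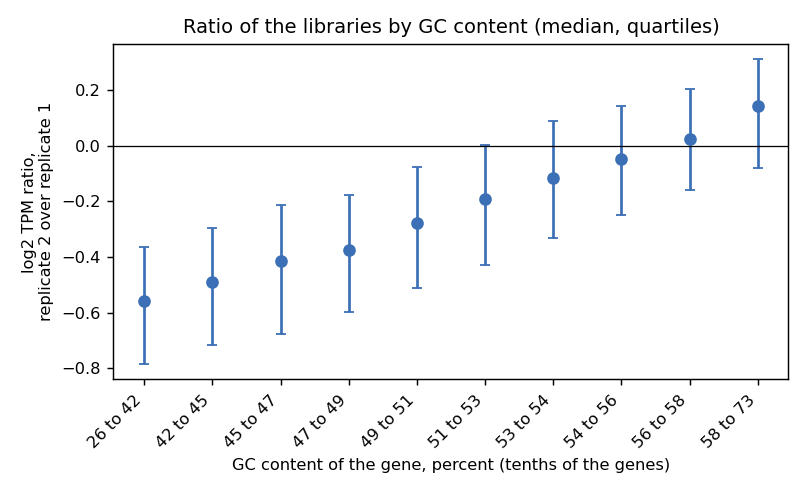
Median log2 TPM ratio of replicate 2 over replicate 1 in 10 bins of the genes by GC content in percent, with bars from the lower to the upper quartile. The medians run from -0.56 in the lowest bin to 0.14 in the highest.

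The share of each gene's abundance held by its top transcript was examined in the transcript tables. Of 3799 genes with at least 2 annotated transcripts and a mean of at least 10 TPM, 2606 (68.6%) had a transcript with at least 50% of the gene's abundance in both libraries, and 1381 (36.4%) had one with at least 80%. The top transcript was the same in both libraries for 3345 genes (88%). A share moved by at least 20 points in 468 genes. The 5 largest moves were in Pfdn4, from 98% to 7.41%, Vps36, from 100% to 19.3%, Eif1ax, from 14.7% to 93.2%, Pfdn2, from 73.5% to 0%, and Slirp, from 0.41% to 70%. Transcripts of a gene share reads, so the shares are estimates and were not tested. A share also depends on the other transcripts of the gene. The Eif1ax transcript fell from 10.29 TPM in replicate 1 to 5.98 TPM in replicate 2 while its share rose. The Vps36 transcript went only from 4.69 to 3.16 TPM. For Pfdn4, Pfdn2 and Slirp the TPM of the transcript moved the same way as its share. The Slirp transcript, of 335 nt, is little longer than the mean fragment of 302.7 nt in replicate 2. It had 132.9 estimated counts there, so its share is less certain still. The Pfdn2 transcript, of 474 nt, is also short.

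The mm9 tables gave the same experiment on another build with Ensembl gene models. Across 33068 genes held in both, mean TPM and the mean mm9 value had a Spearman rho of 0.937. The 5 mitochondrial genes of highest TPM were listed at 0 in the mm9 table. At an irreproducible discovery rate (IDR) of at most 0.1, 16205 of 37310 annotated genes, 264134 of 599181 contigs and 169879 of 914099 splice junctions were retained. Of the retained contigs 29873 (11.3%) lay outside annotated genes on either strand, with a median level of 0.157 against 0.218 for those inside. The 3 highest of these lay on chromosome 3 from 5860318 to 5860841, chromosome 11 from 108872949 to 108873437 and chromosome 6 from 49186436 to 49186623 of mm9, with levels of 4430, 3010 and 2140 in the units of the authors' file. Of all 914099 junctions 168883 matched an intron of the annotation and held 81.7% of junction reads, and of the 169879 retained ones 136959 did. The other 28242125 junction reads include 11258380 and 6356985 of junctions that run between near-identical globin copies. The share of reads outside annotated introns is therefore uncertain.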

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

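The tests of the Y-linked genes, of these genes without the GC trend, and of Xist against the GC trend were chosen after the result was seen, and how the escape-gene, proliferation and first neural list tests were to be read was settled after their values were seen. Signal was found outside the gene counts that the main comparison uses, in spike-ins that serve as library sizes in 1 alternative and in data not used there. ERCC spike-ins held 2.84% of counts in replicate 1 (Wilson 95% interval 2.836 to 2.842) and 1.82% in replicate 2 (1.818 to 1.825). PhiX, a sequencing control, held 0.0764% and 0.0857%. In the mm9 files 29873 reproducible contigs lay outside annotated genes, and 32920 reproducible junctions matched no annotated intron, with a median of 16 reads against 136 for those that did. Spike-ins and phiX are added controls, so their presence tests nothing. No control samples exist, and the contigs and junctions were set against no background.

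Xist differed 526-fold between libraries that the labels both call mixed in sex. The tables argue against the GC trend, since Xist stayed 8.197 log2 units above it, and against decidual or placental tissue, whose 7 marker genes were no higher than 0.06 TPM in replicate 2. A candidate explanation is that the pools differed in sex ratio, with few or no female embryos in replicate 1, since the 4 Y-linked genes had a median log2 ratio of -0.7649 relative to all genes (percentile 0.18 of matched lists), and of -0.4083 (percentile 1.69) once the GC trend was removed. The 5 X-linked genes that escape inactivation had a median of -0.0825 and went both ways (SD 0.248). By the rule written beforehand, a median at or below that of all genes counts against a difference in sex ratio. A requirement that it fall below by more than the SD was added after the value was seen. With that requirement these genes decide nothing. The sex ratio stays a hypothesis, and a mislabelled sample stays open because it was not tested.

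Several neural genes were higher in replicate 2, with a median log2 ratio of 1.19 relative to all genes over 8 genes, where for these low lists a mean of 0.05 TPM and 3 such members were enough. The GC trend is not the whole source, since that median was 1.138 after the trend was removed (percentile 99.92). On 13 members of a second neural list, none of which had been looked at, the median was 1.574 (percentile 100). Traces of nervous tissue may thus be present in replicate 2, although no gene of this second list was above 1 TPM there. Of the first list Tubb3 stood at 3.8 TPM and Map2 at 1.23 TPM in replicate 2. Gap43 of the first list (3.61 and 2.78 TPM) and Chga (0.89 and 0.67 TPM) and Prph (0.5 and 0.32 TPM) of the second were not higher. The median was 0.84 over 5 stomach and gut genes (percentile 98.5), 0.83 over 3 pancreas genes, none of which was called (percentile 97.7), 0.41 over 4 kidney and adrenal genes (percentile 78.9), 0.08 over 5 muscle genes (percentile 58.5), -0.28 over 5 heart genes (percentile 16.3) and 0.05 over 6 genes of a second gut list (percentile 60.7). Reads carried over from other libraries were not tested and stay open, and a biological difference in the liver itself was not tested.

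Proliferation genes had a median log2 ratio of -0.31 and looked lower in replicate 2. That median lay at percentile 16.5 of matched lists, so it was not apart from other genes to begin with, and the medians of -0.08615 relative to all genes without the GC trend and -0.07176 without the length trend decide nothing.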

How the results depend on the processing

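Of the alternatives for results that answer a comparison, 45 were classed as the same, 32 as moved and 2 as reversed. For counts the first class allows clear changes. Examples are genes detected, from 11209 to 15180 at 0.1 TPM, and retained contigs, from 264134 to 177515 at an IDR of 0.01. Those on GC and length trends, pseudogenes, the 1 TPM minimum for called genes, globins added to the erythroid list and the alpha to beta globin ratio were chosen after seeing the data. The cause was not tested for any change below unless the alternative itself leaves fewer or more genes. The beta globin ratio became 9.13 with counts and 6.96 in the mm9 table, and the alpha ratio 12.33 and 11.28. Single replicates gave 8.71 to 8.90 and 13.05 to 13.29. Alpha over beta globin was 0.61 on the log2 scale (0.23 to 1.00 in single replicates) and turned to -0.082 with counts. Erythroid against hepatocyte level went from -0.43 to -2.17 with summed TPM and to 4.17 with globins added. Genes detected fell to 6847 at 5 TPM. Replicate correlation was 0.966 for genes of at least 1 TPM. Called genes numbered 3795 with spike-in sizes, which shift the median log2 ratio to 0.65, 507 with at least 100 counts, 580 with the edgeR exact test, 10788 with no minimum fold and 399 when genes of at least 1 TPM alone were tested. Leaving out processed pseudogenes and genes under 600 nt gave 1020, of which 57.3% were higher in replicate 2 against 44.7%. Lists outside the random range numbered 5 with TMM-normalized counts and 5 without the GC trend, against 3, and the stress list fell to percentile 94.2 with members of at least 5 TPM. The mm9 correlation was 0.863 where both values reached 1, 0.909 as Pearson r, and 0.919 to 0.931 with single replicates. At an IDR of 0.01, 10135 de novo genes, 103214 annotated exons, 4124 de novo and 4039 annotated transcripts and 15454 contigs outside genes were left, against 58940, 211589, 75277, 32373 and 29873. Without a threshold there were 37310 annotated genes, 351001 annotated exons, 95495 annotated transcripts, 599181 contigs, 914099 junctions and 119579 contigs outside genes. A dominant isoform was found for 1381 genes at a share of 80%, 5766 at 1 TPM and 650 at 50 TPM. List differences in the mm9 table were not run, since its columns do not say which library is which, and leaving out a replicate leaves 1 library, with no difference to compute. Depth limits statements on genes near 0.0457 CPM in replicate 2.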

Other observations

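Long noncoding RNAs beside H19 and Meg3 were abundant. These were chosen after their values were seen. Rian, of the same imprinted region as Meg3, stood at 884.8 ± 127 TPM (SD, n = 2), Gas5 at 551 ± 106 TPM, Snhg3 at 160.5 ± 48.7 TPM and Zfas1 at 117.8 ± 18.8 TPM. Protein-coding genes held 96.4% of gene counts in replicate 1 and 97% in replicate 2, and mitochondrial genes 1.45% and 1.7%.

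Of 78 ribosomal protein genes 20 were called lower in replicate 2 and 0 higher (exact binomial test), and 58 were not called. Over all genes 794 of 17906 tested were called lower. The median log2 ratio over the 78 was -0.61 on counts, against -0.002 over all tested genes. On TPM it was -0.55, against -0.23 over all genes. These medians were not set against random lists. Some members are short, such as Rps12 (476 nt) and Rps26 (447 nt), and whether length plays a part was not tested. Spike-in library sizes shift all genes alike by 0.65 log2 units, so the median is read only relative to other genes.

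The spike-ins, of which 57 of 96 had at least 100 counts, correlated between the libraries with Pearson r = 0.988 of log2 counts, across spike-ins, which are not independent replicates. The common coefficient of variation was 28.7% over 71 spike-ins with at least 10 counts and 24.9% over genes.

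In the junction file the junctions of highest count were those of the alpha and beta globin genes. One of them, with 11258380 reads, joins the 2 adult-type alpha globin genes on chromosome 11 (mm9, 32184129 to 32197079) and 1 with 6356985 reads spans the beta genes on chromosome 7 (110961299 to 110975961). Neither matched an annotated intron. The counts lie near those of annotated junctions of the copies themselves, such as 11269518 for alpha and 6662666 for beta globin. The copies are nearly identical, so these counts are uncertain.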
